A study of Mus musculus with 4 samples.

How the data were processed

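RNA was measured in naive CD8 T cells that had been sorted by flow cytometry from the spleens of mice of the BALB/c strain, with 2 samples from Klf13 knockout mice and 2 from wild-type mice. Each sample was hybridised to its own 1-colour Affymetrix array. Per the labels' protocols, 200 ng of total RNA was reverse transcribed with random primers, amplified and labelled with biotin by a whole-transcript method, and every sample had an RNA integrity number above 9. The part of Klf13 that was deleted, the stem cells used to make the allele and the number of backcrosses are not given in the sources used here.

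The deposited values are log2 probe-set values. RMA and Partek are named in the submitters' processing notes, with no versions, and the log2 scale and the range of 1.34 to 13.5 of the deposited table are those of RMA values. RMA corrects the background, makes the probe distributions of all arrays alike by quantile normalization and summarises each probe set. A change of most genes in one direction would therefore be removed, and the folds of dim genes are compressed. No detection calls were used here, so no gene was called absent. Mean levels served to choose 1 probe set per gene, to split and match genes by level and to count dim genes; they also reflect how well each probe set binds, and are no measure of one gene's abundance against another's. The median value of the deposited log2 columns was 4.36 and 4.31 in the knockout arrays and 4.37 and 4.34 in the wild-type arrays. Over the genes tested here the medians lay apart by genotype, at 4.71 and 4.66 in the knockout arrays and 4.59 and 4.61 in the wild-type arrays.

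The table held 35556 probe sets. GEO's platform annotation paired 21789 of them with 1 gene symbol and 1621 with several, and for 12146 it listed none. Symbols were updated through the gene identifier to RefSeq names for the mouse assembly GRCm38.p6, which matched 21698 of the single-gene probe sets. The files name no genome build, so this assembly served only for names and for which genes neighbour Klf13, and no coordinates are given. Each gene was read from its single-gene probe set with the highest mean over the 4 arrays, which gave 19938 genes, of which 999 had more than 1 such probe set. Of the named genes 10 did, and in all 10 the probe sets changed with the same sign, though sizes differed, most for Cycs (-0.30, -0.36 and -1.01). No filter on level was applied. Probe sets of immunoglobulin, Klr, Ifit, Ms4a, Mcpt and histone families can bind transcripts of related genes, so values of single members are uncertain.

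The knockout was compared with the wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, two-sided, Benjamini-Hochberg adjustment over all 19938 genes, threshold 0.05). The prior degrees of freedom were 8.06, so most of the precision of each test came from the spread pooled over genes. The labels do not say whether the 2 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. A second count took genes at an unadjusted p under 0.01 and at least 1.5-fold apart. Fold changes are differences of group means of log2 values, knockout minus wild type, and errors are the SD over 2 arrays or the limma standard error (SE).

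Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists tested. Of 26 lists, the sex-linked one was not tested. Members were also counted by the gene test, over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were the alternatives. Camera compares a list with other genes, whereas fry tests whether a list's genes move, on balance, one way, and compares them with no other genes. The share of genes at an unadjusted p under 0.01 within 10 Mb of Klf13 on each side, Klf13 left out, was compared with all other genes by Fisher's exact test (two-sided, 95% interval); neighbouring genes are not independent, so that p is descriptive.

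These tests, the lists and the rule for naming genes were fixed before the data were examined. Named were Klf13, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap (unnamed clones, Gm and Rik symbols, small RNAs and olfactory genes left out), up to 4 members of each list with the smallest p, and a fixed set of T cell genes, of which 1 is not reported here. Genes named outside this rule are marked where they appear.

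Alternatives were all probe sets tested singly, the mean of a gene's probe sets, the 9969 genes with the higher mean levels, a further quantile normalization, centring of each array on its median, a variance trend with robust moderation, the replicate number as a block, windows of 5 and 20 Mb, a criterion of p under 0.05 near Klf13, and each array left out in turn. Chosen after the data had been seen were a window of 25 Mb, the removal of the genes inside it, 3 further marker lists (granulocyte-monocyte progenitor, pancreatic acinar and plasma cell) and percentiles of list medians among 10000 random lists matched on mean level.

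The gene test was checked on 20 simulated sets with the 19938 genes and the spread of these arrays. It recovered 44.6% of genes changed by 0.5 on the log2 scale and 99.6% of those changed by 1, with 4.82% of its calls false. Camera at the preset correlation called a memory-like list lowered by 0.5 in 20 of 20 simulations, and with an estimated correlation in 0 of 20. The latter therefore had little power with 4 arrays, and its adjusted p-values settle nothing either way. The simulated genes varied independently and all list members were lowered alike. These rates need not hold for the data, where list members can vary together and fold changes varied with level. The number of arrays limits the precision.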

Results

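Transcript levels were measured on 4 arrays in naive splenic CD8 T cells of Klf13 knockout mice (2 arrays) and wild-type mice (2 arrays), all BALB/c. Klf13 is a zinc-finger transcription factor of the SP/KLF family, and the series asks how it bears on memory-like CD8 T cells, which carry memory markers without a known encounter with antigen. Over the 19938 genes, the arrays of a pair correlated with r between 0.993 and 0.998 across genes. The SD of the difference between arrays was 0.191 on the log2 scale for the knockout pair, 0.128 for the wild-type pair and 0.192 to 0.254 between the groups.

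Klf13 itself, on chromosome 7, was 3.10-fold lower in the knockout, at 5.45 ± 0.02 (SD, n = 2) against 7.08 ± 0.10 (SD, n = 2) on the log2 scale (log2 fold change -1.63, SE 0.10, limma adjusted p = 3.75e-05). Both knockout arrays lay below both wild-type arrays. The deleted part of the gene is not known here, and a probe set outside it would check nothing.

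The largest fall was that of Nkg7, which encodes a cytotoxic granule membrane protein and was 22.2-fold lower in the knockout (6.45 ± 0.18 against 10.9 ± 0.03, SD, n = 2, limma adjusted p = 2.76e-08). The T-box factor Eomes, a regulator of memory CD8 T cells, fell 2.73-fold from 8.12 ± 0.01 to 6.67 ± 0.01 (SD, n = 2, limma adjusted p = 3.75e-05). Mpo, the myeloperoxidase of neutrophil granules, rose 3.91-fold from 6.87 ± 0.13 to 8.83 ± 0.07 (SD, n = 2, limma adjusted p = 1.87e-05).

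In all, 448 genes passed the limma test at a Benjamini-Hochberg adjusted p under 0.05, of which 238 were higher and 210 lower in the knockout. At least 2-fold changes were found for 29 of the higher and 16 of the lower genes. At an unadjusted p under 0.01, 1298 genes passed where 199 were due by chance, and 237 of them differed by at least 1.5-fold (139 higher, 98 lower). The count depended on the fit: all 35556 probe sets tested singly gave 39 calls, 14 of them from the 448 genes, and centring each array on its median gave 1088 calls, of which 21.8% were higher in the knockout against 53.1% before. Without knockout replicate 1 the count was 264, without knockout replicate 2 it was 1536 and without wild-type replicate 1 it was 277. Of the called genes that the naming rule gives, 12 passed in every setting, 30 failed only with all probe sets, and 22 also failed in others: Cd244a, Cd69, Cd7, Cd74, Chsy1, Cish, Csf1r, Fan1, Gfi1, Idi1, Ifit2, Il17rb, Il23r, Itga2b, Klf7, Ly6d, Mpeg1, Pf4, St8sia6, Tlcd4, Tnfsf8 and Tyrobp.

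After Nkg7 the largest falls were those of Rcn3, a calcium-binding protein of the secretory pathway (4.77-fold), Klf13 and Dkkl1 (2.77-fold), followed by Eomes. The mast cell protease Mcpt1, Samd3, Fam169b, Cldnd2, the neuronal vesicle protein gene Nsg2, Ms4a4c and the follicular homing receptor Cxcr5 fell 2.49, 2.47, 2.39, 2.34, 2.33, 2.32 and 2.19-fold. The largest rises after Mpo were in the granule proteases Prtn3 (3.28-fold), Ctsg (3.25-fold) and Elane (3.03-fold), the transglutaminase subunit F13a1 (3.21-fold) and the progenitor surface protein Cd34 (3.16-fold). Dhdh rose 2.98-fold, the eosinophil granule gene Prg2 2.89-fold, Igfbp4, which binds insulin-like growth factors, 2.86-fold, Adgrl4, an adhesion receptor of endothelium, 2.77-fold, and Ddit4, an inhibitor of mTOR signalling, 2.65-fold. The immunoglobulin light-chain segment Igkv6-20 rose 2.65-fold, with the doubt that attaches to related segments. Of the 12 falls, 6 were of genes on chromosome 7: Nkg7, Rcn3, Klf13, Dkkl1, Fam169b and Cldnd2.

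**Figure D1:**
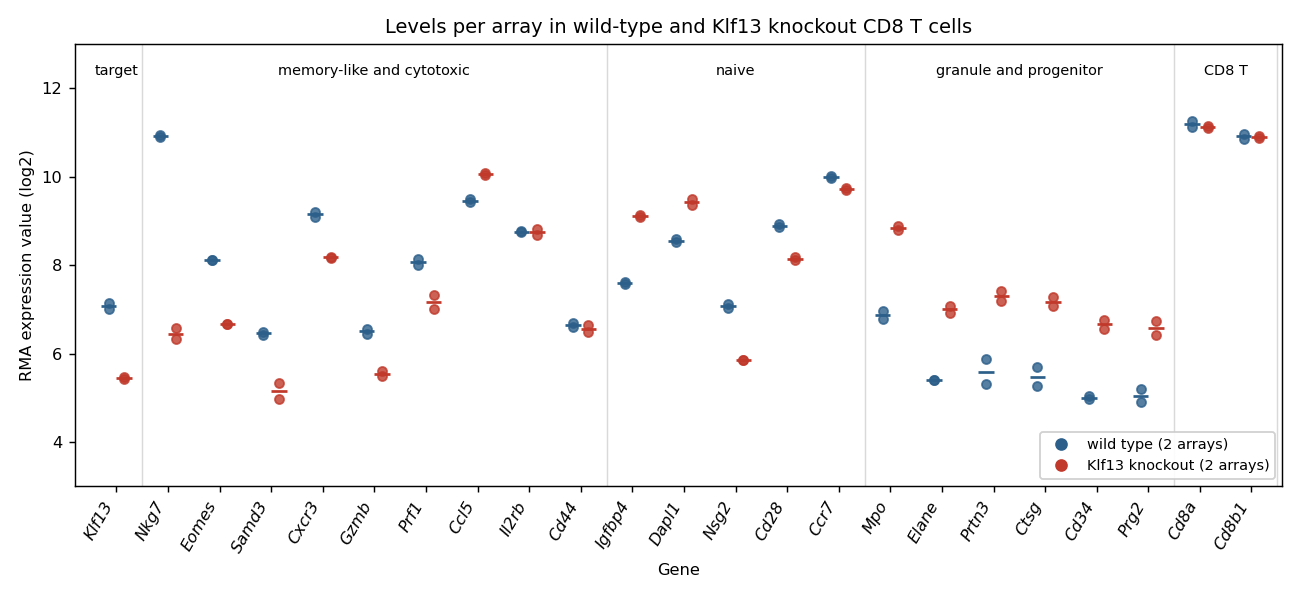
RMA expression values (log2, vertical axis) of selected genes (horizontal axis), with a point for each array and a short line at the mean of the 2 arrays of wild-type (blue) and knockout (red) cells. Nkg7 lay at 10.9 in wild-type and 6.45 in knockout cells, Eomes at 8.12 and 6.67, and Mpo at 6.87 and 8.83.

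Of the memory-like CD8 T list, 26 members were measured, of which 5 fell, 3 rose and 18 did not pass; adjusted over the list alone, 8 fell and 3 rose. Nkg7, Eomes, Samd3 and the chemokine receptor Cxcr3 (log2 fold change -0.97, SE 0.09, limma adjusted p = 5.51e-04) fell, as did Il18rap, an IL-18 receptor chain (-0.42). The chemokine gene Ccl5 rose by 0.60 (SE 0.09, limma adjusted p = 0.00822), and Anxa2 (0.65) and the transcriptional regulator Id2 (0.44) rose as well. Il2rb, the IL-2 and IL-15 receptor chain that marks memory-like cells, differed by -0.01 (limma adjusted p = 0.981), and Cd44, a memory marker, by -0.08 (limma adjusted p = 0.725). Il18rap, Anxa2 and Id2 were named after their values were seen, as members that passed the test. Beside these changes, the medians of neutrophil and B cell markers were 0.21 and 0.25. The list median was -0.15, and limma's camera placed it below other genes (adjusted p = 0.00288). With an estimated correlation the adjusted p = 0.673, but that test called a lowered list in 0 of 20 simulations, so it settles nothing either way. The call was lost among the 9969 genes with the higher mean levels (adjusted p = 0.370) and after a further quantile normalization (adjusted p = 0.142).

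Of 23 measured genes of the cytotoxic effector list, 4 fell, 1 rose and 18 did not pass; adjusted over the list alone, 8 fell and 3 rose. Besides Nkg7, the granzyme gene Gzmb fell by 0.96 and the perforin gene Prf1 by 0.89 on the log2 scale (limma adjusted p = 8.17e-04 and 0.00434), and the serine protease inhibitor gene Serpinb6b, named after its value was seen, fell by 0.58. Ccl5 was the member that rose. The median was -0.22 (camera adjusted p = 0.00689, and adjusted p = 0.787 with an estimated correlation). The call was lost without the genes within 25 Mb of Klf13, Nkg7 among them (adjusted p = 0.0813), with all probe sets (0.0995) and among the 9969 brighter genes (0.109). It was lost without knockout replicate 1 as well. Here too the medians of neutrophil and B cell markers were 0.21 and 0.25. Among 16 NK-type receptors, 1 rose and 0 fell, the same counts as adjusted over the list alone, and the median was 0.01 (camera adjusted p = 0.469). The member that rose was Cd244a (0.55), while Ncr1 (0.41), Klrk1 (-0.26) and Klrb1c (0.22) did not pass.

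The naive T list had 24 measured members, of which 2 rose, 2 fell and 20 did not pass; adjusted over the list alone, 2 rose and 3 fell. Igfbp4 (1.52) and Dapl1 (0.87), both high in naive T cells, rose. Nsg2 (-1.22) and the costimulatory receptor Cd28 (-0.74, limma adjusted p = 0.00309) fell. The lymph node homing receptor Ccr7 differed by -0.27 (limma adjusted p = 0.181). The list median was -0.03 (camera adjusted p = 0.335, and adjusted p = 0.883 with an estimated correlation), and the direction turned upwards among the 9969 brighter genes (adjusted p = 0.921), after a further quantile normalization (0.674) and without knockout replicate 1 (0.874).

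Of 22 genes of the T cell receptor and CD8 core, Cd7 rose (0.52) and the other members did not pass; adjusted over the list alone, 1 rose and 1 fell. The CD8 chains Cd8a and Cd8b1 differed by -0.07 and -0.01, and Cd4 by -0.07; the sign of Cd8b1 turned after a further quantile normalization. Thy1 (-0.34), Ubash3a (-0.28) and Themis (-0.26) did not pass. The median was -0.04 (camera adjusted p = 0.173), and this too turned upwards after a further quantile normalization.

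Genes that respond to IL-4, a cytokine tied to memory-like cells in BALB/c mice, did not move as a group. Of 20 measured, 2 rose, 1 fell and 17 did not pass; adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.608, median -0.05). The cytokine signalling inhibitor Cish (0.51) and the repressor Gfi1 (0.51) rose and Eomes fell, while Ecm1 (0.44) and the receptor chain Il4ra (-0.27, limma adjusted p = 0.228) did not pass. Of 20 genes of the SP/KLF list, Klf7 fell (-0.46) and the others did not pass, among them Klf12 (0.37), Klf11 (0.38) and Sp100 (-0.25), a nuclear body protein that is no member of the family but stood in the list as fixed; adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.608, median 0.03). Of 21 apoptosis regulators, the death receptor Fas fell (-0.62, limma adjusted p = 0.00943) and the others did not pass; adjusted over the list alone, 0 rose and 2 fell (camera adjusted p = 0.469). Its median was 0.002, opposite in sign to the downward camera statistic. Bcl2l1, which encodes a survival protein, differed by -0.02 (limma adjusted p = 0.929), and Birc2 (-0.34), Birc3 (-0.20) and Cflar (-0.18) did not pass.

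Of 32 interferon-stimulated genes, Ifit3 (-0.72) and Ifit2 (-0.59) fell, Ifi44l rose (0.64) and 29 did not pass, Mx1 (-0.36) among them; adjusted over the list alone, 2 rose and 6 fell. The median was -0.10 (camera adjusted p = 0.00288, and adjusted p = 0.715 with an estimated correlation); the call was lost without knockout replicate 1 (0.0900), after a further quantile normalization (0.0711) and among the brighter genes (0.281). Of 24 genes of cholesterol and fatty acid synthesis, Idi1 fell (-0.51) and the others did not pass, including Fdft1 (-0.44), Msmo1 (-0.36) and Insig1 (-0.47); adjusted over the list alone, 0 rose and 3 fell. The median was -0.17 (camera adjusted p = 1.01e-05, and adjusted p = 0.715 with an estimated correlation). Of 55 genes of oxidative phosphorylation, 0 rose and 0 fell, also adjusted over the list alone, with Atp5l (-0.35), Cycs (-0.30), Ndufb6 (-0.29) and Ndufb3 (-0.26) having the smallest p. Other probe sets of Cycs, dimmer than the one used, gave -0.36 and -1.01, and the latter passed when all single-gene probe sets were tested (limma adjusted p = 0.0186). A dimmer probe set of Atp5l passed there too (-0.43, limma adjusted p = 0.0460), while the other Atp5l probe sets did not. The median was -0.13 (camera adjusted p = 4.58e-06, and adjusted p = 0.673 with an estimated correlation), a call lost after a further quantile normalization (0.0711). Beside the medians of these 3 lists, those of neutrophil and B cell markers were 0.21 and 0.25.

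Of 40 cell cycle genes, 0 rose and 0 fell, also adjusted over the list alone. Hmmr (-0.41), Rrm2 (-0.34), Ccne2 (-0.33) and Stmn1 (0.26) had the smallest p, and the median was -0.09 (camera adjusted p = 6.83e-04, and adjusted p = 0.809 with an estimated correlation). For 39 ribosomal protein genes the counts were again 0 and 0, also adjusted over the list alone, with Rps14 (-0.40), Rpl14 (-0.31), Rpl27 (-0.26) and Rpl12 (-0.31) named and a median of -0.07 (camera adjusted p = 0.00429, and adjusted p = 0.563 with an estimated correlation). Both calls were lost after a further quantile normalization (0.441 and 0.348) and among the 9969 brighter genes (0.281 and 0.506), and that of the cell cycle list without knockout replicate 1 (0.126). Fold changes varied with level across all genes: their median was 0.095 among 1994 genes with a median level of 4.28 and -0.092 among 1994 genes with a median level of 6.87. The upper quartile of all probe sets was 6.52 in knockout replicate 1, against 6.63 in knockout replicate 2 and 6.67 and 6.66 in the wild-type arrays. Knockout replicate 2 differed from wild-type replicate 2 (SD 0.192) about as little as from knockout replicate 1 (SD 0.191). Whether knockout replicate 1 alone gave the trend with level was not tested. Among random lists of like level, the cell cycle and ribosomal medians lay at percentiles 32.2 and 36.6. Those of the memory-like, cytotoxic, oxidative phosphorylation, cholesterol and interferon lists lay at 0.34, 0, 0.32, 1.2 and 1.42. Without the genes within 25 Mb of Klf13, which takes out Nkg7, the memory-like median of -0.13 lay at percentile 1.96. The lists that camera placed higher lay at 99.87 or above. CD4 T cell and NK cell markers, which camera did not call, lay at 1.67 and 99.95. The random lists hold unrelated genes, so these percentiles do not allow for members that vary together. The medians of neutrophil and B cell markers on these arrays were 0.21 and 0.25.

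Of 31 immediate-early and activation genes, Cd69, an early activation marker, fell (-0.53) and the others did not pass, among them Egr3 (0.31), Nfkbid (-0.40) and Il2ra (0.38); adjusted over the list alone, 0 rose and 1 fell (camera adjusted p = 0.317, median -0.03, but adjusted p = 0.0241 without knockout replicate 2). Of 18 heat shock and handling stress genes, Ddit4 (1.41) and the chaperone gene Hspa1a (0.97) rose and 16 did not pass, Gadd45b (-0.35) and Txnip (0.26) among them; adjusted over the list alone, 2 rose and 0 fell. Its median of -0.05 was opposite in sign to the camera statistic (adjusted p = 0.878). Of 20 histone genes 0 passed, and adjusted over the list alone 1 rose and 3 fell, with H2ac4 (-0.46), H4c3 (-0.36), H2bc4 (-0.33) and H1f2 (0.33) having the smallest p. The histone median of 0.01 was also opposite in sign to the camera statistic (adjusted p = 0.608).

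**Figure D2:**
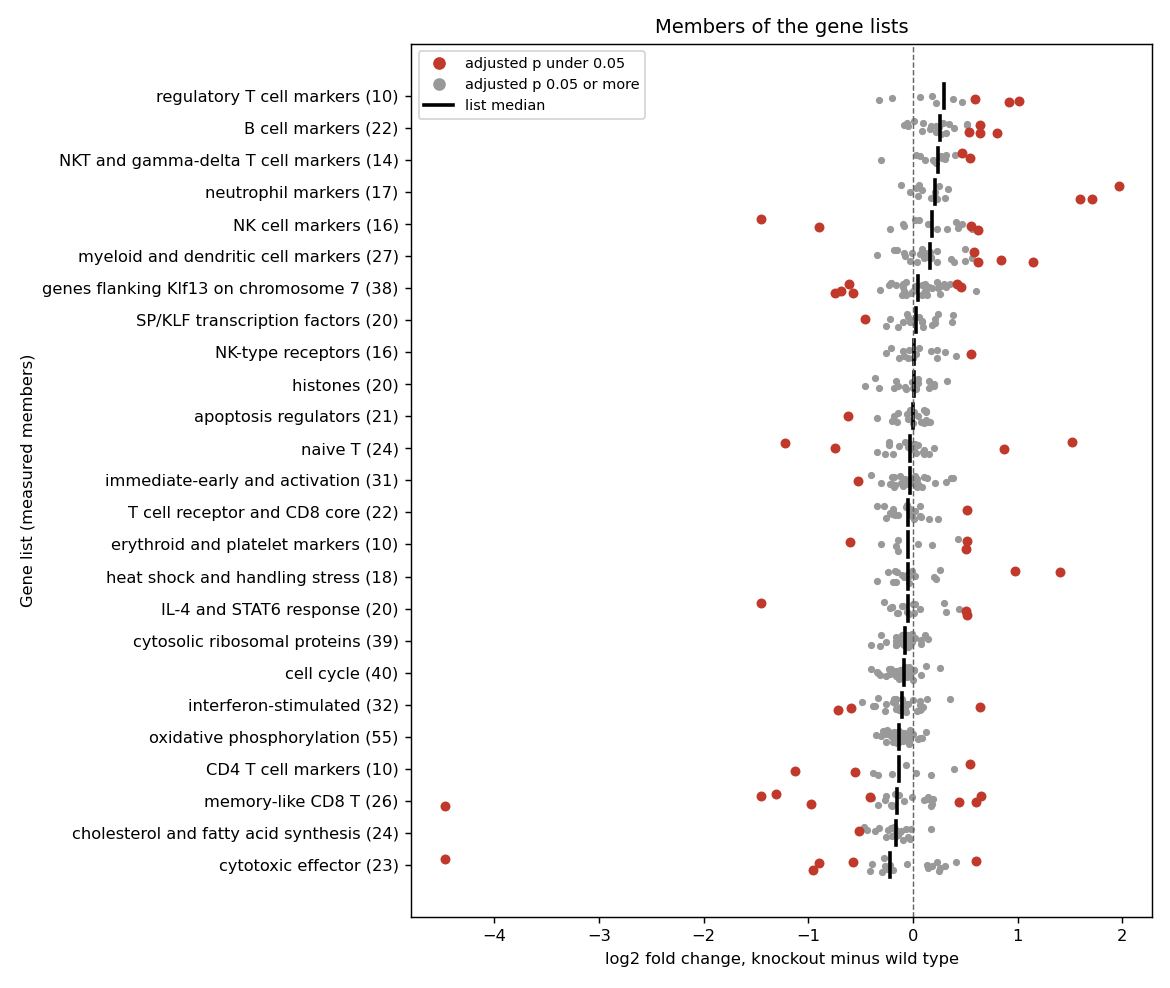
Log2 fold changes, knockout minus wild type (horizontal axis), of the measured members of each tested gene list (vertical axis, number of members in brackets), with members at an adjusted p under 0.05 in red, others in grey and the list median as a black line. The cytotoxic effector list had the lowest median (-0.22) and the regulatory T cell markers the highest (0.30).

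Of 17 neutrophil markers, Mpo, Elane and Prtn3 rose and 14 did not pass, Ngp (0.33) among them; adjusted over the list alone, 4 rose and 0 fell. The median was 0.21 (camera adjusted p = 4.58e-06, and adjusted p = 0.563 with an estimated correlation). Of 27 myeloid and dendritic cell markers, lysozyme Lyz2 (1.15), Mpeg1 (0.84), the adaptor gene Tyrobp (0.62) and the growth factor receptor Csf1r (0.58) rose and 23 did not pass; adjusted over the list alone, 9 rose and 1 fell. The median was 0.16 (camera adjusted p = 9.36e-05, and adjusted p = 0.634 with an estimated correlation). Of 22 B cell markers, Ighm (0.80), Ly6d (0.64), Mzb1 (0.64) and Cd74 (0.53) rose and 18 did not pass; adjusted over the list alone, 10 rose and 0 fell. The median was 0.25 (camera adjusted p = 1.49e-07, and adjusted p = 0.563 with an estimated correlation).

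Of 10 regulatory T cell markers, the integrin Itgae (1.01), Gpr83 (0.92) and the Ikaros family factor Ikzf2 (0.59) rose and 7 did not pass, Nrp1 (0.47) among them; adjusted over the list alone, 5 rose and 0 fell. Itgae is also carried by CD8 T cells. The median was 0.30 (camera adjusted p = 4.24e-04, and adjusted p = 0.673 with an estimated correlation), and without knockout replicate 2 the adjusted p = 0.0501. Of 14 markers of NKT and gamma-delta T cells, the cytokine receptors Il23r (0.47) and Il17rb (0.54) rose and 12 did not pass, including Kit (0.41) and Slamf6 (-0.31); adjusted over the list alone, 3 rose and 1 fell (median 0.24, camera adjusted p = 5.10e-04, and adjusted p = 0.673 with an estimated correlation). Of 10 CD4 T cell markers, Cxcr5 (-1.13) and Tnfsf8 (-0.55) fell, St8sia6 rose (0.55) and 7 did not pass, Zbtb7b (0.39) among them; adjusted over the list alone, 2 rose and 4 fell (median -0.13, camera adjusted p = 0.133). Without wild-type replicate 1 or 2 the CD4 list passed camera (adjusted p = 0.0286 and 0.0371). Of 16 NK cell markers, Tyrobp and Cd244a rose and Eomes and Prf1 fell; adjusted over the list alone, 7 rose and 2 fell (median 0.18, camera adjusted p = 0.105, and adjusted p = 0.0390 after median centring). Of 10 erythroid and platelet markers, Itga2b (0.51) and Pf4 (0.51) of the platelet lineage rose, Tlcd4 fell (-0.60) and 7 did not pass, Epb42 (-0.31) among them; adjusted over the list alone, 3 rose and 2 fell. Its median of -0.05 was opposite in sign to the camera statistic (adjusted p = 0.969). The 5 sex-linked genes had a median of 0.02; the Y-linked Usp9y, Uty, Kdm5d and Eif2s3y lay between 2.12 and 2.85 on every array, and none passed, also adjusted over the list alone; the signs of Uty, Kdm5d and Eif2s3y turned after centring and after a further quantile normalization.

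Genes that neighbour Klf13 on chromosome 7 changed more often than other genes. Within 10 Mb of Klf13 on each side, 14 of 60 genes (23.3%) had an unadjusted p under 0.01, against 1278 of 19795 elsewhere (6.46%; odds ratio 4.41, 95% interval 2.23 to 8.19, Fisher's exact test p = 2.33e-05). The changes went both ways. Among 38 measured genes of a list of neighbours drawn up beforehand, the splicing factor gene Snrpa1 (-0.75), Tarsl2 (-0.69), the chondroitin synthase gene Chsy1 (-0.61) and the nuclease gene Fan1 (-0.58) fell, while Lrrk1 (0.46) and Trpm1 (0.42), named after their values were seen, rose. Adjusted over the list alone, 5 rose and 5 fell, and the median was 0.05 (camera adjusted p = 0.878). Within 25 Mb, a window set after the data had been seen, 27 of 385 genes passed the limma test (7.01% against 2.15% elsewhere; 9 higher, 18 lower), among them Nkg7, Rcn3, Dkkl1, Dhdh, Cldnd2 and Fam169b. Nkg7 and Cldnd2 lie outside the planned windows of 10 and 20 Mb, and Rcn3, Dkkl1 and Dhdh outside that of 10 Mb. Without the genes in that window, 407 genes passed.

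**Figure D3:**
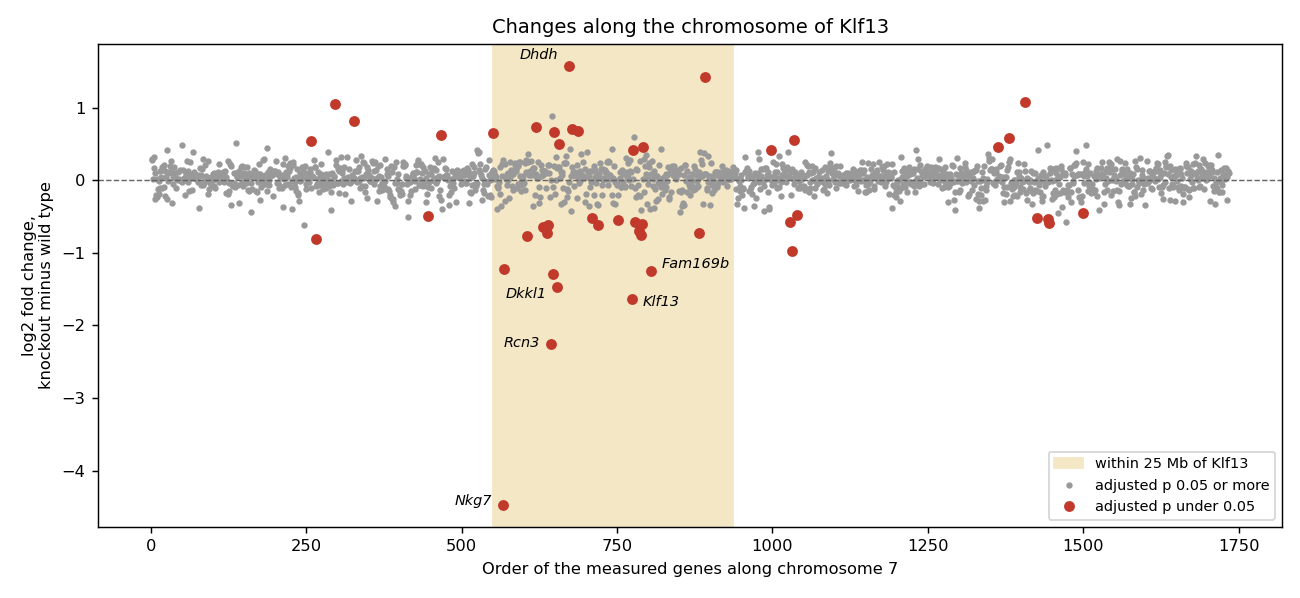
Log2 fold changes, knockout minus wild type (vertical axis), of the measured genes of chromosome 7 in their order along it (horizontal axis, rank), with genes at an adjusted p under 0.05 in red and others in grey. The shaded genes within 25 Mb of Klf13 include Nkg7 (-4.47), Rcn3 (-2.25) and Dhdh (1.58).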

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

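In the test of all probe sets singly, which was planned, 15 probe sets with no single named gene were higher in the knockout than in the wild type (limma adjusted p under 0.05). Of these, 4 share an identical log2 change of 2.22, so the 15 are not separate observations and hold 12 distinct values. Other probe sets that pair with several genes rose by about as much (1.95 and 2.15), so the 12 values need not be separate observations either. The change of 2.22 is larger than that of Mpo (1.97), the largest rise among the named genes. They lie outside the gene comparison, which used single-gene probe sets. Another 10 such probe sets were lower. Of these 25, 9 pair with several genes and the others have no gene listed in the annotation used here, so none was named.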

How the results depend on the processing

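The 25 Mb window and the removal of its genes were chosen after the result was seen; the other settings were planned. Klf13 stayed lower in every setting (-1.70 to -1.56 with an array left out), and the odds ratio near Klf13 stayed above 1 (2.40 to 6.20 over all settings, 2.91 to 5.33 with an array left out). The 448 calls became 39 with all probe sets, 1088 after median centring and 831 with a variance trend; with an array left out they ranged from 264 to 1536. Genes at p under 0.01 and 1.5-fold apart numbered 776 with all probe sets and 239 to 360 with an array left out. With the replicate number as a block the calls numbered 1187. Same-numbered arrays did not deviate together (correlation across genes 0.01), which gives no sign of pairing. The labels do not say whether the numbers pair the samples. With the block the CD4 T cell list also passed camera (adjusted p = 0.0230). The prior degrees of freedom were 8.06 in the main fit, 2.89 with all probe sets, and 18.1 after median centring and with a variance trend. The number of calls moved with them in these settings, but not in all. Without knockout replicate 1 and without knockout replicate 2 the prior degrees of freedom were alike at 5.04, while the numbers of calls lay far apart. The cause of the moves was not tested. With an array left out, the lone array of a group is assumed to vary like the other group. The memory-like list had adjusted p = 0.370 among the 9969 brighter genes, 0.142 after quantile normalization, 0.673 with an estimated correlation, and 7.67e-13 to 0.0241 with an array left out. Of 23 other lists, 11 were called; this became 6 among the brighter genes, 7 after quantile normalization, 0 with an estimated correlation, and 8 to 12 with an array left out. Fry asks another question, whether a list moves one way, with no comparison with other genes; it gave the memory-like list an adjusted p = 0.0877 and called 0 of the other lists. The naive T list turned upwards among the brighter genes (adjusted p = 0.921), after quantile normalization (0.674) and without knockout replicate 1 (0.874; range with an array left out 0.0730 to 0.874).

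Uncalled lists also turned. Among the brighter genes the adjusted p was 0.650 for IL-4 and STAT6, 0.939 for immediate-early genes and 0.906 for histones. After quantile normalization it was 0.857 for IL-4 and STAT6, apoptosis, immediate-early and T cell receptor core genes, and 0.810 for histones. Heat shock genes turned with mean probe sets (0.988) and a variance trend (0.983), erythroid and platelet markers with a variance trend (0.794), and genes flanking Klf13 with the block (0.975) and by fry (0.927). With an array left out, the values ranged from 0.247 to 0.801 (IL-4 and STAT6), 0.0241 to 0.743 (immediate-early), 0.486 to 0.778 (flanking genes), 0.0900 to 0.916 (NK-type receptors), 0.217 to 0.775 (heat shock) and 0.668 to 0.874 (erythroid and platelet). The cause of these turns was not tested. Turned log2 changes of named genes, all uncalled, were after quantile normalization Uty -0.023, Kdm5d -0.022, Eif2s3y -0.021, Il2rb 0.069 and Cd8b1 0.006, and after centring Uty -0.064, Kdm5d -0.065 and Eif2s3y -0.070. With an array left out they ranged over Uty -0.035 to 0.079, Eif2s3y -0.040 to 0.072, Il2rb -0.074 to 0.060, Cd8b1 -0.063 to 0.040, Cd4 -0.36 to 0.23, Usp9y -0.12 to 0.0020, Kdm5d -0.013 to 0.056 and Bcl2l1 -0.062 to 0.015. Of the called named genes, 12 kept their call in every setting (Klf13, Nkg7, Rcn3, Dkkl1, Eomes, Nsg2, Mpo, Elane, F13a1, Cd34, Igfbp4 and Ddit4), 30 lost it with all probe sets alone and 22 lost it elsewhere. Dim genes limit the comparison, since their folds are compressed; of the 1994 dimmest genes, 0 were called.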

Other observations

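The 3 marker lists used here and all tests of explanations were chosen after the results were seen, except the test of genes near Klf13, which was planned. Genes in these paragraphs that the naming rule does not give were picked after their values were seen. Of 40 measured genes of a granulocyte-monocyte progenitor list, 39 were higher, 21 rose past the limma threshold and 1, Nkg7, fell. Besides the granule proteases, the progenitor receptor Cd93 (1.31), Ly86 (1.10), Hp (0.90), Ms4a3 (0.88), Sirpa (0.77) and the cytokine receptor Flt3 (0.68) rose. The list shares 7 members with the myeloid and dendritic cell markers, 4 with the neutrophil markers and 4 with the NK cell markers.

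Of 18 plasma cell genes, 17 were higher and 4 rose, with Ighg3 at 1.35 and Derl3 at 0.51, and 4 are also among the B cell markers. Some plasma cell genes had high values in both groups, with Jchain at 11.05 in the knockout and 10.71 in the wild type, and Igha at 9.54 and 9.41. The 11 plasma cell genes that are in none of the lists fixed beforehand and that the naming rule does not give had a median of 0.13, at percentile 99.5 of matched random lists. Ighg3 and Derl3 are among these 11. Of 27 pancreatic acinar genes, 24 were higher and 7 rose, among them the digestive enzyme genes Cpa1 (1.35), Ctrb1 (1.16) and Cpb1 (0.87). Their levels were low, with Cpa1 at 5.08 ± 0.11 against 3.73 ± 0.004 (SD, n = 2). Among the neighbours of Klf13, Irf3, a factor of interferon induction, fell by 0.73, the glycolytic gene Ldha fell by 0.61, and the amino acid transaminase gene Bcat2 rose by 0.70.

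The first pattern is the higher share of changed genes around Klf13. Alleles of another strain, carried beside the knocked-out gene, are a candidate explanation. The odds ratio within 10 Mb was 4.41, with an interval above 1, but it is the pattern itself and does not tell such alleles from another local cause. The 10 Mb window does not hold Nkg7, which only the 25 Mb window takes in. Whether a lower share of memory-like cells alone lowered Nkg7 cannot be decided from the other 25 members of the memory-like list. Their median was -0.13 against -4.47 for Nkg7. Under such a loss, members that other cells in the sorts also carry would fall less than Nkg7. Dimmer members such as Samd3, at 6.46 in the wild type, also had less room to fall than Nkg7 at 10.9. The overlapping sliding windows of 50 genes are weaker evidence, since the 25 Mb window was set after the data had been seen. Of 763 windows, 14 lay fully within it, and the highest held 9, 8, 7 and 6 called genes. Windows with no gene inside it held at most 8, on chromosome 6, and at most 5 on other chromosomes. No genotypes are analysed here, so an effect of Klf13 on its neighbours stays open.

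The second pattern is the rise of myeloid genes. RNA of granulocyte-monocyte progenitors is a candidate source, although a sort for CD8 is meant to remove such cells. The purity of the sorts is not known here. Of the list members in none of the lists fixed beforehand and outside the naming rule, Cd93, Ly86 and Igsf6 were left out because their values had been seen. The other 18 were all higher, and their median of 0.35 lay at percentile 100 of matched random lists. Hp, Ms4a3, Sirpa and Flt3, picked above after their values were seen, are among these 18. Pancreatic RNA beside it may be a further source, as the acinar genes other than Cpa1 and Ctrb1 also lay at percentile 100. Just 4 of the 27 acinar genes had a log2 level above 4 in the wild type, but a source in the knockout samples alone would leave them low there. In the knockout the acinar genes lay between 2.14 (Spink1) and 5.17 (Ctrl), so that test still rests mostly on dim probe sets. Mpo lay at 8.83 ± 0.07 (SD, n = 2) in the knockout and 6.87 ± 0.13 in the wild type. Expression by the CD8 T cells themselves cannot be told apart from RNA of other cells, because the T cell receptor and CD8 core median of -0.044 would not show a small admixture.

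The third pattern is the fall of 5 of the 26 memory-like genes, while 3 rose and 18 did not pass. A lower share of memory-like cells as the whole cause is argued against by the 3 list members that rose, Ccl5, Anxa2 and Id2, though other cells in the sorts could carry these. Alleles near Klf13 acting on the genes beside them, as the whole cause, are argued against by the 4 members farther than 25 Mb away that fell, Eomes, Samd3, Cxcr3 and Il18rap. Without the genes in that window camera's adjusted p was 0.0314, against 0.00288 with them. With them and an estimated correlation the adjusted p = 0.673, from a test with little power here that settles nothing either way. An effect of Klf13 on Eomes and Cxcr3 within the cells stays open, as does a partial loss of memory-like cells. Of the 3 splits of the 4 arrays into 2 and 2, the real one was the only 1 with calls, 448 against at most 0 in the others, and 3 splits are too few for a share under 0.05.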
